A study of Mus musculus with 6 samples.

How the data were processed

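Gene expression was measured by sequencing in 6 libraries of a mouse cell line, 3 control and 3 MAOA-KO, grouped by the labels' titles and descriptions. The deposited table holds 15836 genes with whole-number read counts per library, FPKM, and the authors' comparison as a log2 fold change, a p-value, an adjusted p-value and the −log10 of both, per the file headers. The genome build is mm10 per the submitters' processing notes and GRCm38.p6 per the file headers. The aligner, the counting tool, the strand setting and the authors' test are not given in the sources used here. The labels' protocol describes enrichment of small RNA before library preparation, whereas 98.2% of the counts of control replicate 1 and 98.3% of those of MAOA-KO replicate 1 fell on protein-coding genes in the deposited table. Each row has a total of at least 10 counts, so the table had been filtered before deposit. The deposited FPKM values follow from the deposited counts, the table's own totals and 1 length per gene, with a largest relative deviation of 3.2e-05.

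The authors' deposited columns call 9111 genes at an adjusted p under 0.05, 4447 higher and 4664 lower. DESeq2 1.42.0 with default settings, run here on the counts, gave log2 fold changes within 2.8e-05 of the deposited ones and placed 0 rows on the other side of 0.05. The values in the report come from the counts.

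Each row's listed locus and the transcript length implied by its deposited counts and FPKM were checked against GENCODE M21 (GRCm38). Of 15814 rows whose identifier is in that annotation, 15652 had the length of a transcript of the named gene within 1 base. In 4 rows, among them those named Maoa, Ccl5 and Tmem127, the listed locus was that of another gene, and in all 4 the implied length was that of the gene at the listed locus. Locus, strand and implied length of these rows point to one gene, and identifier, symbol and description to the other. The table itself does not show which set of columns the counts belong to. The named columns were used for all fits, as the design fixed before the data were examined named Maoa by its symbol, both rows are given for Ccl5, 1 further row and 1 further named gene are not reported here, and naming by locus was added as an alternative.

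Differential expression was computed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (13243 tested), libraries scaled with TMM factors (0.968 to 0.972 in the controls, 1.03 in the MAOA-KO libraries), and a robust quasi-likelihood model with group as its term was tested, with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the estimate divided by the square root of F. CPM values are scaled by the TMM factors, and errors of CPM are SDs over 3 libraries. The common biological coefficient of variation was 0.0332. Library totals ran from 18631359 to 26645441 counts. Replicate pairs differed by more than counting error, with a mean chi-square per gene of 2.10 to 4.91 within groups. The replicates were treated as separate samples, although this excess does not show that they are separate cultures.

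In all, 36 gene lists were fixed before the data were examined. Those with at least 5 tested members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Annotation terms were not tested, since the table carries none. Named genes followed a rule fixed in advance: Maoa and Maob; the 6 highest and 6 lowest log2 fold changes among called protein-coding genes with a mean of at least 5 CPM in the higher group, no overlap between groups and an established symbol; and up to 3 members of each list central to the study and up to 2 of each other list, by lowest p. Genes of lists without a call may be left out, and the marker genes of both groups beyond the rule were chosen after their values were seen.

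The replicate numbers were checked for pairing, since the labels number the samples 1 to 3 in each group. Deviations from the group means of same-numbered samples correlated across genes at 0.330, 0.195 and 0.169, each above 0.1, which was taken as a sign of pairing. Control replicate 3 correlated at 0.222 with MAOA-KO replicate 2, more than with its own number, so the pairing stays uncertain. The labels do not say what a number shares. The main fit does not use the pairing, and the replicate number enters as a block only among the alternatives.

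On simulated counts with the real genes' means and library sizes and 200 genes changed, for the comparison of MAOA-KO with control over 13243 genes, the test recovered 66% of genes changed 1.2-fold, 88% at 1.5-fold, 92% at 2-fold and 96% at 4-fold, with 3.9% false calls. The simulation gave every gene the common dispersion and changed far fewer genes than the 9781 called in the data. These shares may therefore not hold for the real comparison. In the list test on the same simulated data, a moved list was called and 0 of 20 unmoved lists were.

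Alternatives fixed in advance were DESeq2, limma-voom, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, protein-coding genes only, a non-robust fit, a test against a 1.2-fold change, each library left out, and the replicate number as a block; for lists also an estimated correlation, fry and a prior count of 0.5. Alternatives added after the data were seen were library totals without factors, a correction for GC content and length, counts thinned to the smallest total, the last 2 also with the block, leaving out the ribosomal RNA-like gene model CT010467.1, and naming the 4 rows by locus.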

Results

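RNA from 6 samples of a mouse cell line that the labels call CAF, an abbreviation used in this field for cancer-associated fibroblast, was sequenced, with a pancreatic tumour given as the tissue. The 3 control libraries carry a wild-type genotype label, and the 3 MAOA-KO libraries carry a knockout label for Maoa, the mitochondrial enzyme that oxidises serotonin and noradrenaline. One label field of the MAOA-KO libraries speaks of knockdown instead. Total counts were 23735244, 24666170 and 25116027 in the controls and 21111577, 26645441 and 18631359 in the MAOA-KO libraries, so that 3 counts correspond to between 0.110 and 0.156 CPM (counts scaled by library total and TMM factor). These floors cover counting error only. No label says whether the replicates are separate cultures, and p-values here measure the spread between these 6 libraries only.

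The comparison of MAOA-KO with control asks how the transcriptome of these cells differs where Maoa is disrupted, in a study whose title concerns serotonin and immune exclusion. The row that carries the name and identifier of Maoa (ENSMUSG00000025037) does not list the Maoa locus, which is chromosome X, 16619698 to 16687818 on the plus strand in GRCm38. The deposited counts and FPKM of this row also imply a transcript length other than the 4167 bases of the annotated Maoa transcript. Whether its counts are those of Maoa could not be established from the table.

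The row named Maoa was lower in the 3 MAOA-KO libraries than in the 3 controls and was not at 0. It fell from 49.0 ± 0.922 to 24.9 ± 0.639 CPM (mean ± SD, n = 3 per group). Its counts were 1124, 1151 and 1221 in the controls and 545, 664 and 490 in the MAOA-KO libraries, with a log2 fold change of -0.98 ± 0.05 (SE) and an adjusted p of 3.46e-15 in edgeR's quasi-likelihood test. An exact two-sided permutation test gave p = 0.1, the smallest that 3 samples against 3 allow. Maob, which encodes the paralogous enzyme, had 2 to 4 counts per control library and 4 to 6 per MAOA-KO library and was not tested.

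The rows named Ccl5 and Tmem127 listed each other's locus. The row named Ccl5 (ENSMUSG00000035042), a chemokine that attracts T cells, lists chromosome 2, 127247908 to 127261107, which is the locus of Tmem127, and rose from 79.3 ± 2.44 to 119 ± 3.50 CPM, with a log2 fold change of 0.58 ± 0.04 and an adjusted p of 3.14e-12 in edgeR. The row at the Ccl5 locus, chromosome 11, 83525778 to 83530518, is named Tmem127 (ENSMUSG00000034850) and fell from 9.51 ± 0.889 to 2.60 ± 0.131 CPM, with a log2 fold change of -1.87 ± 0.11 and an adjusted p of 1.29e-13. The direction of Ccl5 therefore depends on whether the name or the locus of a row is followed. Names below are those of the table, and 4 of the 15814 rows with an annotated identifier listed a locus apart from that of the named gene.

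**Figure D1:**
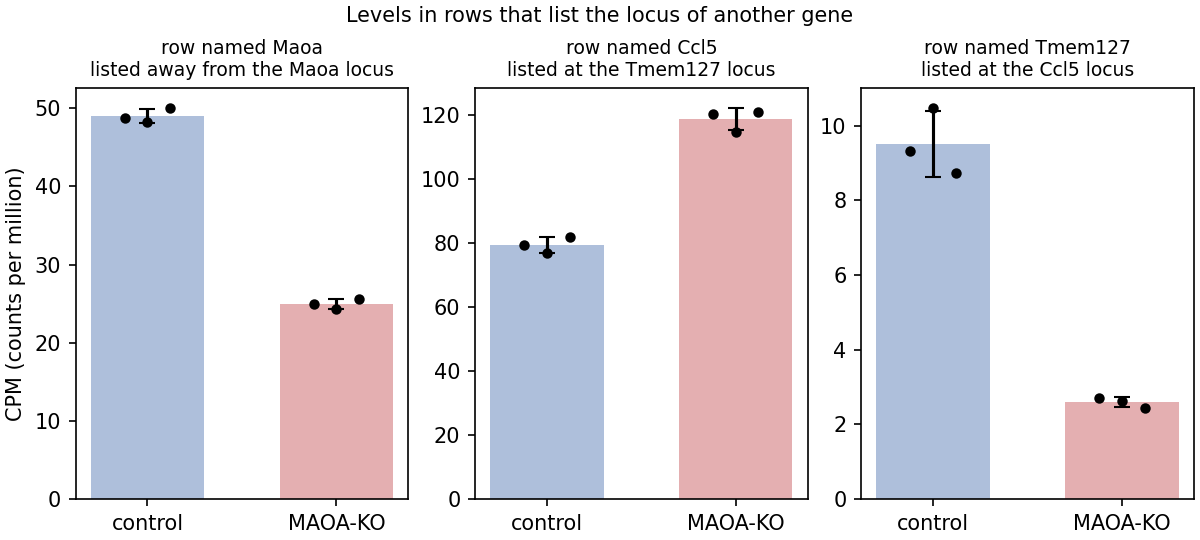
CPM in the rows named Maoa, Ccl5 and Tmem127, none of which lists the locus of its named gene. Bars are means, error bars the SD and points the 3 libraries of each group. The rows named Maoa and Tmem127 were lower in MAOA-KO, and the row named Ccl5 was higher.

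Ppargc1a, a transcriptional coactivator of mitochondrial genes, showed the largest rise among the genes selected by the naming rule, and Serpinb2, an inhibitor of plasminogen activators, the largest fall. Ppargc1a went from 0.393 ± 0.108 to 15.0 ± 1.08 CPM (n = 3 per group), a log2 fold change of 5.24 ± 0.16 (adjusted p = 4.82e-20, edgeR). Rragd, a GTPase that acts on mTORC1 at the lysosome, rose from 3.85 ± 0.872 to 114.9 ± 1.83 CPM, 29.6-fold. The complement genes C1s1 and C4b rose 15.3-fold and 11.6-fold, and both have close paralogs with which reads may be shared. Adamts9, a matrix protease, rose 13.4-fold, and Ptgds, a prostaglandin D synthase, 12.9-fold. Serpinb2 went from 26.8 ± 0.887 to 1.01 ± 0.171 CPM, a log2 fold change of -4.75 ± 0.11 (adjusted p = 3.31e-22). Acsbg1, an acyl-CoA synthetase, was 19.7-fold lower, the adhesion receptor Sele 17.1-fold, the mannose receptor Mrc1 16.5-fold, the laminin chain Lamb3 15.7-fold and the peptidase Klk10 13.0-fold lower. The 3 libraries of one group lay apart from the 3 of the other for each of these 12 genes, as the rule required.

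**Figure D2:**
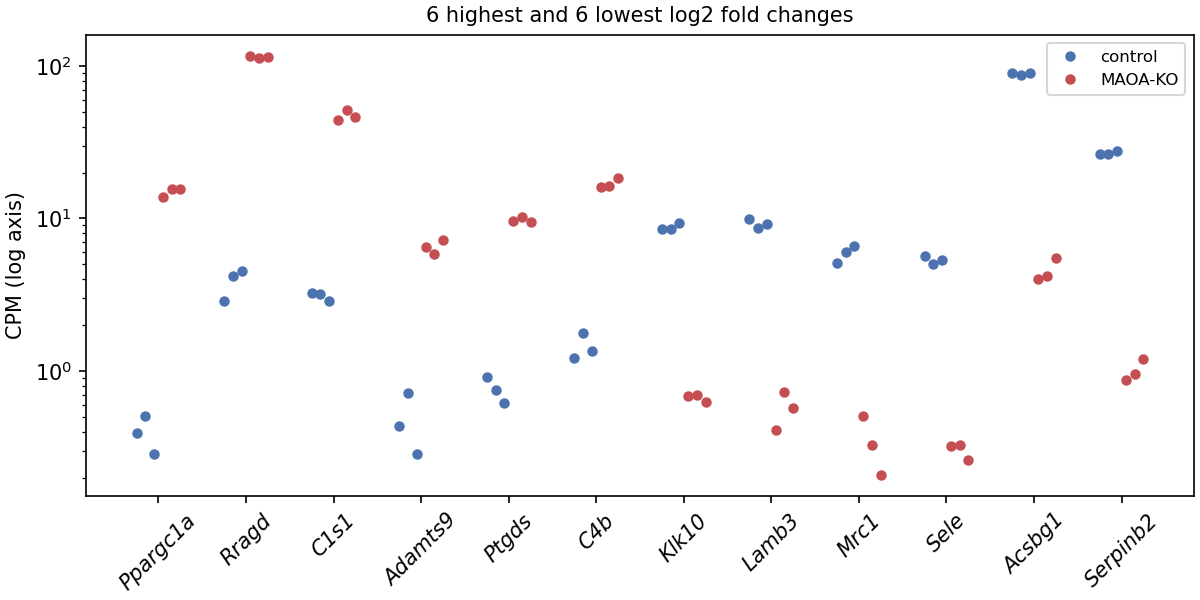
CPM of each library, on a log axis, for the 6 genes with the highest and the 6 with the lowest log2 fold change under the naming rule, ordered by fold change. The 3 control and the 3 MAOA-KO libraries do not overlap for any of them; Rragd rose 29.6-fold and Acsbg1 was 19.7-fold lower.

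Of 13243 genes tested, 9781 passed an adjusted p of 0.05 in edgeR, 4900 higher and 4881 lower in MAOA-KO. A log2 fold change of at least 1 was reached by 989 of the higher genes, and one of at most -1 by 869 of the lower genes. Against a change of 1.2-fold, 3120 genes were higher and 2959 lower. The groups did not overlap for 75.1% of the tested genes, where chance gives 10%.

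Cell cycle genes were lower in MAOA-KO. All 28 members of the G2 and M phase list fell, with a median log2 fold change of -2.68. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, went from 108.3 ± 1.84 to 10.1 ± 0.471 CPM, and Cdc20, an activator of the anaphase-promoting complex, from 88.4 ± 1.45 to 10.0 ± 0.383 CPM. Of 29 S phase genes 27 fell and 1 rose, with a median of -1.03. Rrm2, a subunit of ribonucleotide reductase, fell by 2.80 ± 0.06 on the log2 scale, and Mcm5, part of the replicative helicase, by 2.19 ± 0.06. Both lists passed limma's camera test with its preset correlation (adjusted p = 8.75e-15 for G2 and M phase and 1.83e-09 for S phase). With an estimated correlation these gave an adjusted p of 0.0761 and an adjusted p of 0.0587.

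Genes of the unfolded protein and integrated stress responses were lower as well: 25 of 26 fell, with a median log2 fold change of -0.81 (camera adjusted p = 1.35e-09; adjusted p = 0.0761 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 7393 ± 311 to 2347 ± 54.2 CPM, and Creld2 from 257.7 ± 5.21 to 67.4 ± 1.83 CPM. Of 21 immediate early genes 14 fell and 2 rose (median -0.60; camera adjusted p = 0.00179; adjusted p = 0.356 with an estimated correlation). Egr1 was 5.76-fold lower and Myc 2.42-fold lower.

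The hypoxia and glycolysis list fell in 23 of its 29 tested members and rose in 4 (median -0.40; camera adjusted p = 0.00122; adjusted p = 0.356 with an estimated correlation). The lactate transporter Slc16a3 was 2.95-fold lower and the glucose transporter Slc2a1 2.21-fold lower. Of 22 tested NRF2 targets 16 fell and 3 rose (median -0.44; camera adjusted p = 0.00530; adjusted p = 0.446 with an estimated correlation). Abcc1, an efflux transporter, was 2.03-fold lower, whereas the glutathione transferase Gstm2 rose 2.86-fold. The list of senescence-linked genes holds mostly secreted factors and inhibitors, and also nuclear genes such as Lmnb1 and Hmgb2. It fell in 11 of 14 tested members and rose in 2 (median -0.48, camera adjusted p = 0.0311, or 0.304 with an estimated correlation). Its leading members were Hmgb2, a chromatin protein, 3.50-fold lower, and the EGFR ligand Areg, 10.7-fold lower. As the list mixes genes of different roles, its direction gives no reading on senescence.

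Sterol synthesis and MHC class I genes were higher in MAOA-KO. Of 22 sterol synthesis genes 20 rose and 1 fell, with a median log2 fold change of 0.83 (camera adjusted p = 1.52e-06; adjusted p = 0.0694 with an estimated correlation). Sc5d went from 73.7 ± 2.87 to 176 ± 0.943 CPM and Cyp51 from 74.1 ± 0.374 to 167 ± 2.56 CPM. Of 22 MHC class I presentation genes 16 rose and 4 fell, with a median of 0.62 (camera adjusted p = 0.00157; adjusted p = 0.356 with an estimated correlation). B2m, the invariant light chain, went from 1156 ± 5.70 to 2713 ± 21.1 CPM. H2-Q4 rose 2.87-fold and H2-Q6 3.69-fold, with reads that near-identical class I genes may share.

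**Figure D3:**
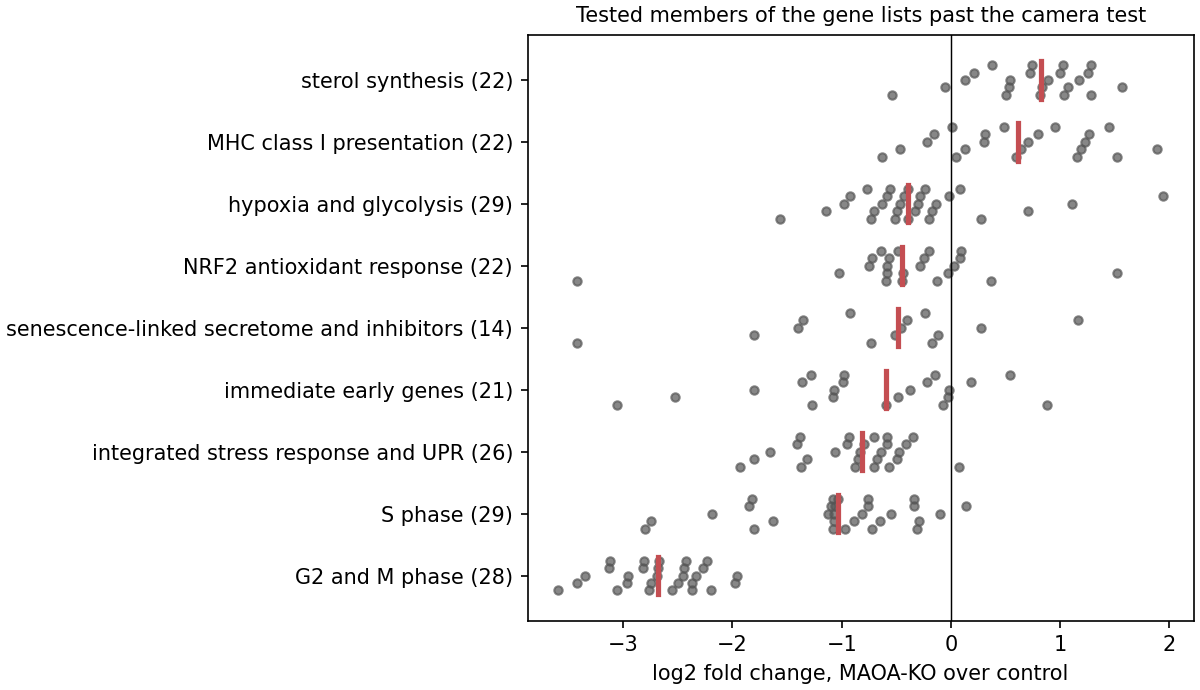
log2 fold change, MAOA-KO over control, of each tested member (grey points) of the 9 gene lists past the camera test, with the number tested in brackets and the median as a red line. The medians run from -2.68 for G2 and M phase to 0.83 for sterol synthesis.

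MHC class I presentation aside, the tested lists closest to the study's subject did not pass the camera test, with members that moved in both directions. Of 10 tested T and NK cell chemoattractants 4 rose and 4 fell (median 0.15; camera adjusted p = 0.894). With rows named by locus, 3 rose and 5 fell (median -0.19; adjusted p = 0.556). Cxcl10 fell by 2.71 ± 0.07 on the log2 scale and Cxcl16 rose by 1.02 ± 0.08. Of 12 tested neutrophil and monocyte chemoattractants 9 fell and 3 rose (camera adjusted p = 0.119), with Cxcl5 2.53-fold lower, Il34 1.36-fold lower and Ccl2 1.65-fold higher. Of 22 genes of serotonin and monoamine handling 9 had a row and 6 were tested, and Slc6a4, Tph1 and Ddc had none. Of those tested 3 rose and 2 fell (camera adjusted p = 0.893), with the row named Maoa among the falls. Tph2, among the rises, had low levels, 0.268 CPM in the controls and 0.589 CPM in MAOA-KO. Tgm2, the transglutaminase that can attach serotonin to proteins, rose 1.46-fold, and the vesicular transporter Slc18a1 rose from 0.691 ± 0.229 to 2.38 ± 0.324 CPM.

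Of 42 interferon-stimulated genes 23 rose and 12 fell (camera adjusted p = 0.174): Parp14 rose 1.80-fold, and Isg20 and Oasl1 were 1.89-fold and 1.78-fold lower. Among 19 tested immune checkpoint and suppressive mediators 7 rose and 9 fell (camera adjusted p = 0.665), with Ptgs2, the inducible cyclooxygenase, 5.53-fold lower, Lgals3 1.51-fold lower and Lgals1 1.49-fold lower. Of 27 TGF-beta response genes 16 fell and 7 rose (median -0.24; camera adjusted p = 0.0755), and Ltbp2 and Id3 had log2 fold changes of -3.32 ± 0.10 and -1.25 ± 0.05. The inflammatory CAF markers had 3 members that rose and 7 that fell of 12 tested (camera adjusted p = 0.515). C3 and C4b, which the list holds, rose 6.19-fold and 11.6-fold, and Ptgs2, which it holds too, was 5.53-fold lower. The myofibroblastic CAF markers had 5 that rose and 8 that fell of 16 tested (median -0.13; camera adjusted p = 0.893), with Col12a1 6.85-fold higher, Mmp11 2.00-fold higher and Tpm2 1.74-fold lower. Among 17 tested collagen-associated genes 6 rose and 7 fell (camera adjusted p = 0.748), and Sparc and Col5a1 were 1.62-fold and 1.63-fold lower. In total 9 of the 30 lists with at least 5 tested members passed, 2 higher and 7 lower, and with an estimated correlation 0 passed. Adjusted over the list alone, 3 monoamine handling genes fell and 21 ribosomal protein genes rose, against 2 and 20 over all genes tested, and the other lists kept their counts.

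Marker genes describe the cells in both groups. Of 19 fibroblast identity genes 14 lay under 10 CPM in each library or had no row, among them Col1a1, at 0.417 to 2.04 CPM, and Pdgfra, at 0.469 to 1.56 CPM. Vim lay between 1771 and 3477 CPM and Col3a1 between 116 and 131 CPM, and Fbln2 and Twist1 between 122 and 162 CPM and between 33.8 and 36.6 CPM. The keratins Krt8 and Krt18 lay between 437 and 903 CPM and between 686 and 953 CPM, and Krt19 between 84.3 and 360.0 CPM, while Epcam and Cdh1 reached at most 0.451 and 2.83 CPM. Krt19, Krt8 and Vim were 4.06-fold, 1.91-fold and 1.92-fold lower in MAOA-KO. The tested fibroblast identity genes, 2 higher and 7 lower of 11, did not pass the camera test (adjusted p = 0.0755), nor did the tested epithelial genes, 3 higher and 5 lower of 11 (adjusted p = 0.332). The macrophage and leukocyte list had 4 lower of 5 tested (camera adjusted p = 0.0746), with Mrc1 at 5.88 CPM in the controls. Only these 5 of its 22 genes had a row, and Ptprc and Csf1r had none. Over all 6 libraries Cd68 lay between 44.5 and 55.7 CPM and Cd14 between 23.2 and 26.8 CPM.

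**Figure D4:**
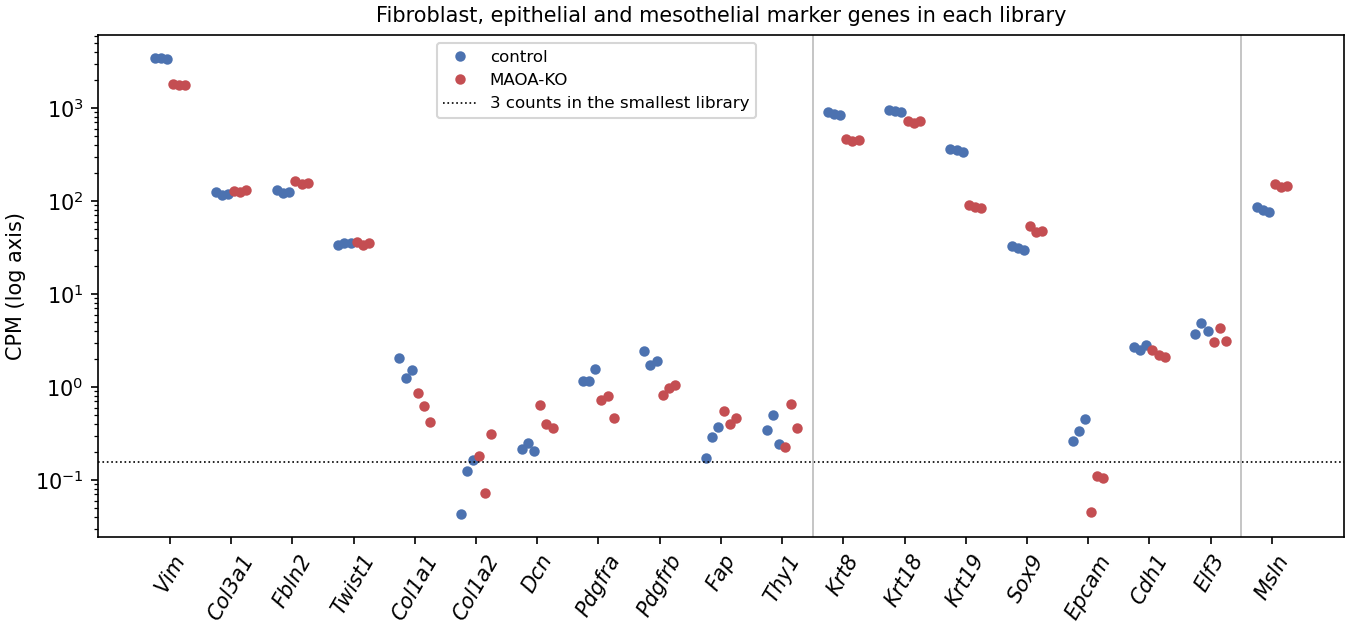
CPM of each library, on a log axis, for marker genes of fibroblasts (left), pancreatic epithelium (middle) and mesothelium (right), with a dotted line at the level of 3 counts in the smallest library. Krt8 and Krt18 lie at 437 CPM or more in all libraries, and Col1a1, Dcn and Pdgfra below 10 CPM.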

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

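Alternatives with library totals only, GC and length correction, thinned counts, CT010467.1 left out and the 4 rows named by locus were chosen after seeing the data. The main comparison called 9781 genes. Tested against a 1.2-fold change, 6079 were called, 3120 higher and 2959 lower, as that test asks for a larger change. Without 1 library the count lay between 9357 and 9772, with 4667 to 4864 higher and 4650 to 4908 lower. The replicate block gave 10205 genes and changed no call of a named gene or list. GC and length correction gave 10078 genes, or 10186 with the replicate block, and equal depth 9411, or 9780 with the replicate block. GC and length correction kept 9068 of the 9781 calls and reversed the sign of 46 (9100 and 53 with the replicate block). With library totals only, 5759 genes were higher and 4044 lower, against 4900 and 4881. Of 1931 repeats of single named genes under 23 alternatives, 1930 kept direction and side of the threshold. The exception was Ccl5, which had a log2 fold change of -1.87 when rows were named by locus, by construction. Most named genes were selected for a low p or an extreme fold change in the same comparison, so few could change side. Naming by locus alters only 4 rows, so most repeats under it could not change. The log2 fold change of the row named Maoa lay between -0.99 and -0.96 without 1 library, and between -1.17 (GC and length correction) and -0.89 (library totals only) over all alternatives that keep the table's names. The 9 list calls stood without any 1 library (2 higher, 7 lower each time). With an estimated correlation 0 lists were called, 0 higher and 0 lower. For S phase, sterol synthesis and the senescence-linked list the estimate (-0.0312, -0.0193 and -0.0349) lay under the preset 0.01. Their camera p still rose, for S phase from 1.83e-10 to 0.00196 before adjustment, so a higher correlation does not account for these losses. In the other called lists the estimate lay above the preset, and the cause was not tested. With fry, which does not compare a list with other genes, 24 were called, 7 higher and 17 lower; there the myofibroblastic CAF markers (adjusted p = 0.00167; range over its alternatives 0.00167 to 0.969) and the NF-kB feedback and targets (adjusted p = 0.0342; range 0.0342 to 0.887) turned from lower to higher. Depth limits genes near 0.110 to 0.156 CPM, the level of 3 counts. The count filter reached above that level, as Maob, at up to 0.219 CPM, was not tested, and it left 2593 genes untested. A 1.2-fold change was recovered for 66% of simulated genes.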

Other observations

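The gene groups in this and the next paragraph were drawn up after the leading genes of the comparison had been seen, so each was tested on the members not looked at until then; tests on the exchanged rows and on the marker genes were chosen only after the result was seen. Lysosomal genes were higher in MAOA-KO: of 50 tested genes for lysosomal enzymes and membrane proteins 47 rose and 2 fell. The 47 members not seen before had a median log2 fold change of 0.84 (camera adjusted p = 3.79e-14; adjusted p = 0.0129 with an estimated correlation). Tpp1, Hexa, Lamp1 and Gla rose by 1.58 ± 0.04, 1.45 ± 0.04, 1.24 ± 0.03 and 1.90 ± 0.05 (SE). Complement genes rose in 10 of 11 tested members, and the 6 not seen before had a median of 1.54 (camera adjusted p = 0.0328; adjusted p = 0.209 with an estimated correlation). Clu rose by 2.09 ± 0.04, while the receptor gene C3ar1 fell by 2.49 ± 0.14.

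Aminoacyl-tRNA synthetase and ribosome biogenesis genes were lower, whereas ribosomal protein genes, a list fixed in advance, rose in 20 and fell in 13 of 38 tested members (median 0.10; camera adjusted p = 0.392). All 20 aminoacyl-tRNA synthetases fell, and the 18 not seen before had a median log2 fold change of -0.55 (camera adjusted p = 1.80e-06; adjusted p = 0.0129 with an estimated correlation). Of 30 ribosome biogenesis genes 26 fell and 0 rose, with a median of -0.40 over the 29 not seen before (camera adjusted p = 7.28e-07; adjusted p = 0.0129 with an estimated correlation); Nolc1 and Nop56 fell by 0.73 ± 0.04 and 0.66 ± 0.04. Targets of ERK signalling not seen before had a median of -0.35 (15 of 21 fell; camera adjusted p = 0.00634; adjusted p = 0.209 with an estimated correlation), with Dusp6 and Spry4 lower and Spry1 higher. FoxO targets not seen before had a median of 0.27 (camera adjusted p = 0.0110, or 0.0936 with an estimated correlation). Of these 19 genes 11 rose, such as Pik3ip1 and Fbxo32, and 2 fell, Errfi1 and Cited2. The others, among them Cat and Sod2, did not pass.

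The 9781 genes called came from the real grouping, 1 of the 10 splits of the 6 libraries into 3 and 3. The 9 other splits gave 0 genes by edgeR, with 16 to 63 genes at an unadjusted p under 0.05, and 3 of them also part all 3 same-numbered pairs. Each of these 9 splits puts control and MAOA-KO libraries together on both sides. The difference between the groups then counts as spread, which by itself leaves few genes to call. The 0 calls therefore cannot decide whether chance plays a part, and with 10 splits the share cannot fall under 0.05.

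The rows named Maoa, Ccl5 and Tmem127 are among 4 rows that list the locus of another gene. All 4 have the implied transcript length of the gene at the listed locus, which gene names exchanged between rows would give, and 0 have that of the named gene, which locus and length exchanged with the counts in place would give too. Both remain open, since no column of counts identifies its gene. Under the first, the counts of each of these rows would be those of the gene at its listed locus, and the counts in the row named Maoa would not be those of Maoa. No biological explanation applies.

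Mitotic genes were lower in MAOA-KO in all 28 members of the list. The choice among the scalings tried does not account for it, as the median log2 fold change was -2.59 at the highest, with library totals only. The TMM factors were 0.968 to 0.972 in the controls and 1.03 in the MAOA-KO libraries, so leaving them out could move a list only slightly. A change shared by most genes cannot be seen with any of these scalings. A growth state of the cultures apart from the Maoa loss, such as density or medium, stays open: FoxO targets not seen before had a median of 0.27, in the direction it predicts, and the design has no second pair of cultures to part it from the genotype. An effect of Maoa disruption also stays open and untested.

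Of the 19 fibroblast identity genes 14 lay under 10 CPM in each library or had no row. Among them Col1a2, Dcn, Fap and Thy1 reached at most 0.313, 0.642, 0.550 and 0.658 CPM. The keratins Krt8, Krt18 and Krt19 were high in all 6 libraries, while Vim, Col3a1, Fbln2 and Twist1 stayed at 33.8 CPM or more. Other keratins of the epithelial list were lower, Krt7 at 1.79 to 14.8 CPM and Krt20 at 0.104 to 0.694 CPM. The CAF marker lists above were tested in these cells, whose fibroblast origin the markers leave open. Of the 15 non-keratin genes of the epithelial list, 6 had no row. Of the other 9, 7 stayed under 1% of the level of Krt8 in each library, a mark chosen after the values were seen. Among them were Elf3 (at most 0.995%), Cdh1 (0.537%), Muc1 (0.345%) and Epcam (0.0541%). Sox9 reached 11.4% and Ocln 5.37%, so not every one of these genes was low beside Krt8. Admixed epithelial cells stay open as an explanation. The levels these genes have in an epithelial cell of this tumour are not known here, so the values cannot decide it. Cells of another origin than fibroblasts stay open too: of the 10 non-keratin mesothelium markers 2 reached 10 CPM, Msln at 75.3 to 151 CPM and Ezr, which many cell types express. Only mesothelium markers were set against this explanation, so it was not examined for other origins. No biological explanation was tested.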
